A study of Caenorhabditis elegans with 8 samples.

How the data were processed

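RNA was extracted from whole C. elegans animals with Trizol and a column, and ribosomal RNA was depleted with Ribo-Zero, per the labels' protocols. The genome build was WBcel235 and the tools were STAR 2.0.4b, Subread and featureCounts 1.45, per the submitters' processing notes. The annotation release, the strand setting and the handling of reads with several matches were not given in the sources used here. Each of the 8 libraries had its own table of 46726 genes, and no column of per-sample values was left unused for want of a sample label.

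The deposited count column held whole read counts per gene, not normalised, per the file headers. The deposited CPM column was the authors' CPM, the count scaled to the library's summed counts, and the deposited RPKM column was the authors' CPM per kilobase of exon length, per the file headers. Recomputing both from the counts and lengths gave the deposited values for all 46726 genes of every library, to within 1e-06 of the value or of 1, whichever was larger. Tests used the counts only. CPM values in the results section were recomputed with TMM-scaled library sizes, given as mean ± SD over the 2 libraries of a group.

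Gene symbols, biotypes and overlaps came from a WBcel235 annotation and a table of gene names. Of the 46726 gene identifiers, 46364 were in that annotation, and 61.72% of these had the same chromosome, start and end, so the authors' annotation was another release. Coordinates are those of the files. Because no strand setting was stated, reads of a gene and of an overlapping gene on the other strand cannot be told apart, and such overlaps are named beside the genes they concern. The near-identical copies numr-1 and numr-2 could not be evaluated: numr-1 had 0 counts and numr-2 had 0 to 3 counts in every library, and how reads that match both copies were counted is not known.

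Total counts ran from 17681352 to 29586507 per library. A count of 3, taken as the floor that an unseen gene allows, was 0.1014 to 0.1697 CPM. Ribosomal RNA genes took 1.84 to 3.93% of the counts and protein-coding genes 95.1 to 97.3%. The floor covers counting error only, and reads without molecular identifiers are not independent molecules. The 95% intervals of log2 changes come from the quasi-likelihood SE with 8.79 to 12.3 degrees of freedom, so they include the spread between cultures. The 4 groups were taken from the sample labels, with 2 libraries in each. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom over genes between any 2 libraries was 9.27, and within a group it was 24.01 or more.

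The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3). Genes passed filterByExpr by group (minimum count 10, minimum total 15), which left 15818. All 8 libraries entered 1 fit with TMM scaling, robust dispersion estimates and 4 group means. The 5 contrasts, each tested 2-sided, were cadmium in the wild type, cadmium in the mutant, mutant against wild type without cadmium, mutant against wild type with cadmium, and the interaction, which is the cadmium effect in the mutant minus that in the wild type. Adjusted p is Benjamini-Hochberg over the genes of a contrast, and genes under 0.05 are said to have risen or fallen. Standard errors (SE) of log2 fold changes are the absolute fold change divided by the square root of F. A response is called hizr-1-dependent only where cadmium in the wild type and the interaction both passed with opposite signs. These contrasts share the wild-type libraries, so the count was set beside 20 simulations without dependence. In these, genes that passed for cadmium in the wild type had their fitted effect in both genotypes, and other genes had no cadmium effect.

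Gene lists fixed beforehand numbered 31. They covered metal-response genes, the CDR family, zinc transporters, cadmium detoxification, other metals and haem, glutathione S-transferases, cytochrome P450 enzymes, UDP-glycosyltransferases, the heat shock response, endoplasmic reticulum and mitochondrial chaperones, antioxidant enzymes, hydrogen sulfide and cysteine metabolism, the proteasome, antimicrobial genes, C-type lectins, osmotic stress, fat metabolism, collagens, vitellogenins, ribosomal proteins and histones. Further lists were markers of sperm, oocytes with early embryos, zygotic embryos, moulting, intestine, muscle, neurons, hypodermis and the dauer or starved state. Some genes sit in several lists: cdr-1, cdf-2, ttm-1 and mtl-1 are metal-response genes and also belong to the CDR, zinc transporter and dauer lists. The symbol cdr-5 was read as hrg-2, its present name, and members without a match (daf-21, sqrd-2, vet-4, opt-2 and bus-8) were left out. Lists with at least 5 tested genes were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with a correlation estimated from the data and limma's fry. Adjusted p is Benjamini-Hochberg over the lists of a contrast.

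The genes named were set by rule. They were hizr-1, mtl-1, mtl-2, cdr-1, cdf-2, ttm-1, numr-1 and numr-2 in every contrast. Added to these were, per contrast, up to 8 genes per direction with the largest log2 change among those that passed, with a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups compared, and no non-coding RNA. From each list came up to 4 members that passed, by smallest adjusted p, or, where none passed, up to 2 with the highest mean CPM. Any gene named outside this rule is said to have been chosen after its values were seen.

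The test was checked on simulated data built from the means and library sizes of the 15818 genes, with 200 genes changed. With gene-wise dispersions, cadmium in the wild type recovered 10%, 40%, 84% and 98% of genes changed 1.5-, 2-, 4- and 8-fold, and the interaction recovered 2%, 10%, 64% and 88%. Between 10.3 and 16.5% of the calls were false across the 5 contrasts with gene-wise dispersions, above the nominal 5%, and 5.6 to 8.51% with dispersions on the trend. For cadmium in the wild type, camera at the preset correlation called the 1 shifted list and 0 of the 29 unchanged lists. The simulated genes varied independently, so this check cannot show how the preset test behaves on lists whose genes move together. In the data the correlation estimated for that contrast ran from -0.0434 (osmotic stress) to 0.957 (vitellogenins).

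The contrasts, tests, lists, naming rule and most alternatives were set before the data were examined. Those alternatives were another scaling (DESeq2-type size factors or library size only), no filter or a stricter one (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, protein-coding genes only, mitochondrial and rRNA genes left out, 1 surrogate variable (sva 3.50.0), the libraries of a contrast alone, an adjusted p under 0.01, a log2 fold change of at least 1, and leaving out each library in turn. Chosen after seeing the data were a fit with the sperm list median of each library as covariate and a fit with every library thinned to the smallest total. The covariate comes from the same libraries, so where it differs between the groups compared it takes up part of the contrast. The replicate numbers were checked for pairing, and the results of the check and of the block are in the closing section.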

Results

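The series measured whole-animal RNA of C. elegans in wild-type cultures and in cultures of a mutant that lacks hizr-1 function through allele am286, each with and without cadmium chloride. HIZR-1 is a nuclear receptor that activates genes of the high zinc response, and the series asks how cadmium, a toxic metal, acts through it. Mixed-stage populations grown for 4 days were moved to noble agar minimal medium with concentrated E. coli OP50 as food. They stayed there for 16 to 18 h at 20 °C with 0 or 100 mM cadmium chloride as the labels write it. That unit is in doubt and could not be checked here, since 100 mM is far above the micromolar doses usual for C. elegans. Each of the 4 groups held 2 samples, each pooled from 10 plates, which the series design calls biological samples. The plates of both genotypes were grown in parallel, so p-values measure the spread between parallel cultures, pooled over the 4 groups.

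Total counts of replicates 1 and 2 were 29416027 and 23143603 for the wild type without cadmium, and 27323411 and 21940131 for the wild type with cadmium. They were 26044429 and 17681352 for the mutant without cadmium, and 29586507 and 19791267 for the mutant with cadmium. Adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named, and log2 fold changes are given with their SE.

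The targeted gene, hizr-1 (WBGene00013976, chromosome X, 11318278 to 11321076, + strand, 13 exon blocks), was lower in every mutant library than in every wild-type library. Its counts in replicates 1 and 2 were 57 and 52 in the wild type without cadmium and 101 and 77 with cadmium. In the mutant they were 18 and 7 without cadmium and 20 and 18 with cadmium. For hizr-1 the mutant lay below the wild type by a log2 change of -1.99 ± 0.377 without cadmium (adjusted p = 0.0931) and of -2.16 ± 0.347 with cadmium (adjusted p = 0.00635). Cadmium changed hizr-1 itself by 0.62 ± 0.31 in the wild type, which did not pass (adjusted p = 0.472).

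Cadmium raised both metallothionein genes, cdr-1 and 2 zinc transporter genes in the wild type. The metallothionein genes mtl-1 and mtl-2, whose products bind zinc and cadmium, went from 5.47 ± 1.03 to 286 ± 5.18 CPM and from 10.9 ± 3.82 to 413 ± 2.49 CPM (SD, n = 2). The cadmium-responsive gene cdr-1 went from 1.06 ± 0.161 to 126.2 ± 25.7 CPM. The zinc transporter gene cdf-2, which stores zinc in gut granules, went from 3.12 ± 0.222 to 16.6 ± 1.79 CPM, and ttm-1, a zinc exporter, from 26.1 ± 0.139 to 49.1 ± 6.86 CPM. Their log2 fold changes were 5.70 ± 0.188 for mtl-1 (adjusted p = 9.48e-09), 5.26 ± 0.301 for mtl-2 (7.76e-05), 6.87 ± 0.297 for cdr-1 (1.8e-07), 2.41 ± 0.224 for cdf-2 (0.000195) and 0.91 ± 0.163 for ttm-1 (0.0433). Of the 6 tested metal-response genes 5 rose, all but hizr-1. This list was the only one of 31 that passed camera with an estimated correlation (adjusted p = 0.00574, camera preset 4.41e-100).

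**Figure D1:**
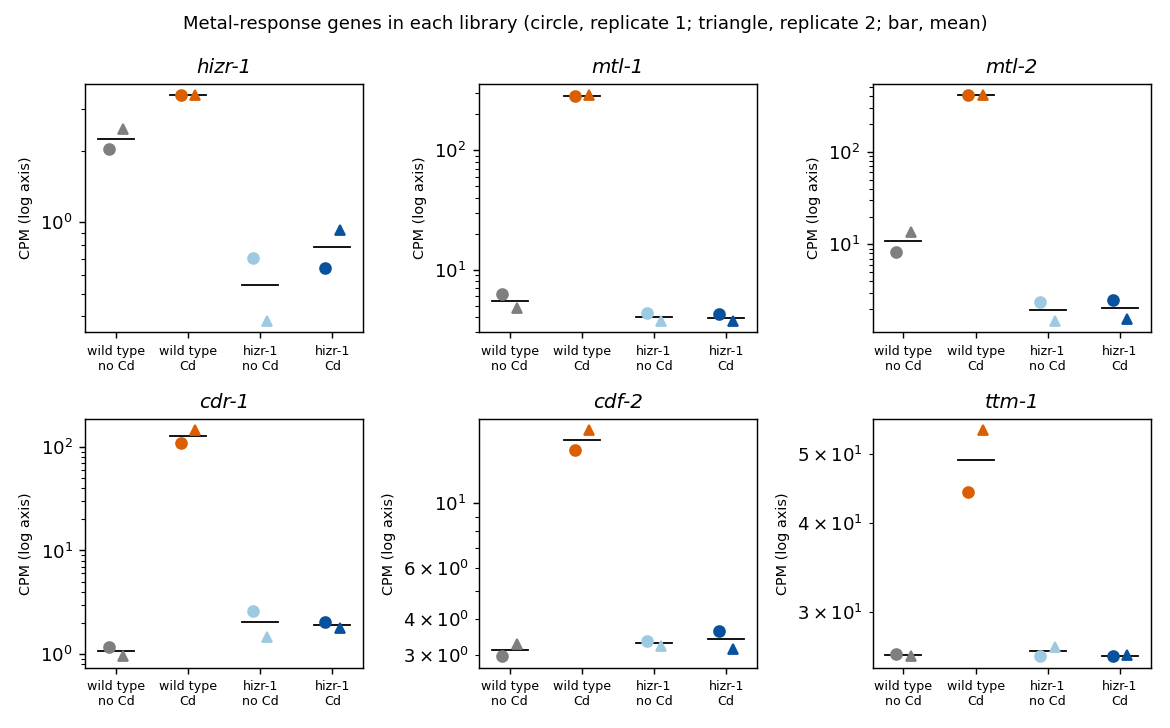
TMM-normalised CPM (log axis) of hizr-1 and 5 metal-response genes in each of the 8 libraries, by group, with replicate 1 as a circle, replicate 2 as a triangle and the group mean as a bar. For mtl-1, mtl-2, cdr-1, cdf-2 and ttm-1 both wild-type cadmium libraries lie above the other 6 libraries.

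In all, 37 genes rose and 8 fell with cadmium in the wild type, out of 15818 tested. The split was 72 higher and 143 lower by DESeq2, 180 and 396 with no filter on low counts, and 110 and 289 with only the 4 libraries of the contrast. Several of the strongest lie close together on the chromosome. T08G5.1 (5.84 ± 0.463, adjusted p = 6.73e-05) occupies V 14018766 to 14020332 on the + strand, beside mtl-2 at 14018272 to 14018643 on the - strand. The glutathione S-transferase gene gst-38 (3.57 ± 0.276, adjusted p = 6.73e-05) lies at V 15915168 to 15916079 and cdr-1 at 15921361 to 15922820. On chromosome II, cyp-13A4 occupies 9795848 to 9797740 and cyp-13A7 9803620 to 9805510. These pairs were picked out after their values were seen.

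A few genes of enzymes that modify and conjugate foreign compounds rose as well. Of 66 cytochrome P450 genes 6 rose and 0 fell, or 11 and 0 adjusted over the list alone. Among them were cyp-13A4 (5.26 ± 0.361, adjusted p = 2.11e-05), cyp-14A4 (4.05 ± 0.305), cyp-13A7 (4.43 ± 0.401) and cyp-33C7 (2.22 ± 0.239). Of 41 glutathione S-transferase genes gst-38 and gst-33 (2.39 ± 0.368) rose, or 6 adjusted over the list alone. The UDP-glycosyltransferase genes ugt-1 (1.49 ± 0.202) and ugt-16 (1.23 ± 0.205) rose among 62, or 3 higher and 1 lower adjusted over the list alone. Camera's preset test placed these lists above other genes (adjusted p = 3.98e-18 for P450s, 1.26e-11 for glutathione S-transferases and 0.000959 for UDP-glycosyltransferases). With an estimated correlation they did not pass (adjusted p = 0.142, 0.517 and 0.539). Of 14 cadmium detoxification genes pgp-1, an ABC transporter gene, rose (1.06 ± 0.176), and the list did not pass camera (adjusted p = 0.175). In the CDR family cdr-1 alone rose among 6, or 2 adjusted over the list alone (camera adjusted p = 1.04e-14, and adjusted p = 0.0592 with an estimated correlation). Of 19 zinc transporter genes 2 rose, cdf-2 and ttm-1, in both counts (camera adjusted p = 0.00845, and adjusted p = 0.517 with an estimated correlation).

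Other genes higher with cadmium included the invertebrate lysozyme gene ilys-2 (5.15 ± 0.562, adjusted p = 0.000858), which had 4 and 3 counts without cadmium and 155 and 115 with it. It and irg-4, an infection response gene (1.66 ± 0.163, adjusted p = 0.000346), were the 2 of 57 antimicrobial genes that rose, or 3 adjusted over the list alone (camera adjusted p = 6.17e-08, and adjusted p = 0.539 with an estimated correlation). The gut protease gene cpr-1 went from 242 ± 56.6 to 853 ± 80.7 CPM (adjusted p = 0.000614) and was the 1 of 19 intestinal markers that rose, in both counts (camera adjusted p = 0.00598, and adjusted p = 0.539 with an estimated correlation). Both carotenoid oxygenase genes rose, bcmo-2 by 2.26 ± 0.185 and bcmo-1 by 3.04 ± 0.405, and so did thn-2 by 2.05 ± 0.258 and T16G1.6 by 2.56 ± 0.259. These 4 were named after their values were seen, except in the interaction contrast, where the rule takes bcmo-2 and T16G1.6. Among the genes that fell were cth-1, a cystathionine gamma-lyase gene (-1.05 ± 0.175, adjusted p = 0.0286), and fat-7, a stearoyl-CoA desaturase gene (-0.94 ± 0.168, adjusted p = 0.0433). Also lower were catp-4 (-1.69 ± 0.299) and Y51H7C.1 (-1.53 ± 0.247). With the sperm list median as covariate, a fit chosen after seeing the data, 20 of the 37 higher and 0 of the 8 lower genes still passed, and 0 of the 8 passed without any one of the 4 cadmium libraries. All 8 stayed below 0 in 21 alternatives, with a log2 change of -1.223 to -0.865 for cth-1, -1.03 to -0.775 for fat-7, -2.118 to -1.08 for catp-4 and -1.767 to -1.24 for Y51H7C.1. It was -1.86 to -1.21 for K09F6.3, -3.767 to -2.09 for F57F4.1, -3.195 to -1.60 for C33F10.11 and -2.958 to -1.66 for H05L14.1, these 4 named after their values were seen.

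The classical stress lists held few or no genes that passed. Of 13 cytosolic heat shock genes 0 passed, or 4 higher adjusted over the list alone. The median of that list was -0.01 and its mean 0.26 (camera adjusted p = 0.0917), and the abundant members hsp-90 and hsp-1 were at -0.19 ± 0.192 and -0.34 ± 0.18. Nor did any of 15 endoplasmic reticulum chaperone genes (camera adjusted p = 0.239), 11 mitochondrial chaperone genes (0.315), 22 antioxidant genes (0.212), 31 proteasome genes (0.106), 8 osmotic stress genes (0.315) or 13 genes of other metals and haem (0.212). The hydrogen sulfide and cysteine list had cth-1 lower among 16 (camera adjusted p = 0.516), and the fat list had fat-7 lower among 34 (camera adjusted p = 0.657, median -0.00462, mean 0.0808). Among 148 collagen genes 0 passed (camera adjusted p = 0.1, median 0.0586, mean -0.254), and among 33 histone genes 0 passed (camera adjusted p = 0.2). C-type lectins (121 genes, camera adjusted p = 0.02), vitellogenins (6 genes, 1 lower adjusted over the list alone, camera adjusted p = 0.00123) and ribosomal proteins (76 genes, camera adjusted p = 0.00293) held 0 genes that passed over all genes. With an estimated correlation these 3 had adjusted p = 0.55, 0.539 and 0.754. The ribosomal list was placed above other genes with the sperm covariate and without wild-type replicate 2 lacking cadmium.

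Among markers of cell types and stages, sperm genes moved the most. All 63 sperm genes were lower with cadmium, with a median log2 change of -1.85, but 0 passed, also adjusted over the list alone (camera adjusted p = 3.63e-25, and adjusted p = 0.517 with an estimated correlation). The median log2 CPM of that list was 1.08 and 2.53 in the wild-type libraries without cadmium and -0.452 and 0.835 in those with cadmium. Among the oocyte and early embryo (29 genes), zygotic embryo (14), moulting (20) and neuron (23) markers 0 passed. Their medians were -0.23, 0.33, 0.24 and 0.35, and camera's adjusted p were 3.75e-05, 0.0035, 0.00983 and 0.000192. With an estimated correlation these became adjusted p = 0.539, 0.517, 0.621 and 0.539, and with the sperm covariate the moulting list was placed below other genes. Muscle (21 genes, camera adjusted p = 0.516) and hypodermis markers (12 genes, camera adjusted p = 0.0777) did not pass. In the dauer and starvation list (14 genes) mtl-1 rose, or 2 genes adjusted over the list alone (camera adjusted p = 7.63e-09, and adjusted p = 0.142 with an estimated correlation).

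Of the 45 genes, 16 passed in every alternative that tested them, among them mtl-1, mtl-2, cdr-1, cdf-2, gst-38, cpr-1 and the P450 genes cyp-13A4, cyp-13A7, cyp-14A4 and cyp-33C7. The count was 17 without wild-type cadmium replicate 1, 25 without replicate 2, 28 without either mutant cadmium library, and 423 (73 higher, 350 lower) without wild-type replicate 1 of the cultures lacking cadmium.

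In the hizr-1 mutant the same exposure left mtl-1, mtl-2, cdr-1, cdf-2 and ttm-1 near their level without cadmium. Metallothionein gene mtl-1 had 4.01 ± 0.412 CPM without and 3.98 ± 0.374 CPM with cadmium, mtl-2 had 1.93 ± 0.642 and 2.03 ± 0.678 CPM, and cdr-1 had 2.05 ± 0.808 and 1.93 ± 0.178 CPM. The 95% intervals of the log2 change were -0.415 to 0.397 for mtl-1, -0.742 to 0.903 for mtl-2, -0.731 to 0.521 for cdr-1, -0.452 to 0.545 for cdf-2 and -0.375 to 0.333 for ttm-1. Their upper bounds lie below the lower bounds in the wild type, which were 5.29, 4.57, 6.23, 1.93 and 0.556. For hizr-1 the intervals were wide and overlapped, with -0.459 to 1.36 in the mutant and -0.0514 to 1.29 in the wild type. Of the 6 tested metal-response genes 0 passed, also adjusted over the list alone, and camera gave an adjusted p of 0.822.

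Across all genes 4 rose and 1 fell with cadmium in the mutant. The glutathione S-transferase gene gst-38 rose by 1.93 ± 0.26 (adjusted p = 0.0454), from 6.49 ± 0.601 to 24.7 ± 8.46 CPM, and asp-14, an aspartyl protease gene, by 1.31 ± 0.153 (adjusted p = 0.0249), from 189 ± 2.13 to 469 ± 42.2 CPM. The haem-signalling protease gene hrg-7 fell, with a log2 change of -1.11 ± 0.153 (adjusted p = 0.0454). The other genes that rose were the non-coding RNA genes srpr-1.2 (1.32 ± 0.19) and srpr-2.1 (1.38 ± 0.198), which lie outside the naming rule and were named after their values were seen. The annotated bodies of asp-14 and hrg-7 overlap those of fah-1 and C15C8.7. Camera's preset test placed 4 lists above and 4 below other genes. Above were glutathione S-transferases (41 genes, 34 above 0, adjusted p = 9.25e-07), antimicrobial genes (57 genes, 51 above 0, 5.22e-12), ribosomal proteins (76 genes, 71 above 0, 1.44e-08) and histones (1.44e-08). Below were UDP-glycosyltransferases (adjusted p = 0.000629), fat metabolism (0.000916), other metals and haem (0.00248) and the heat shock response (0.00616). None of the 8 passed with an estimated correlation (adjusted p = 0.673 to 0.92). Without mutant replicate 2 lacking cadmium the ribosomal list was placed below other genes. That library stood apart, with median log2 CPM of 9.347 for ribosomal and 2.485 for antimicrobial genes, against 10.22 to 10.33 and 3.339 to 3.596 in the other mutant libraries. None of the 5 genes passed in every alternative: by edgeR 0 passed without mutant cadmium replicate 1, either mutant library lacking cadmium or either wild-type cadmium library, 1 without mutant cadmium replicate 2, and 14 without either wild-type library lacking cadmium. Unadjusted p was below 0.05 at 282 genes, fewer than the 791 expected by chance, and at 168 to 1189 genes where 1 of the 5 libraries that gave 0 was left out. DESeq2 called 11 genes and limma-voom 1, and RLE size factors in edgeR gave 2 higher and 1 lower.

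The interaction contrast asked directly whether the cadmium response differed between the genotypes. The difference, mutant minus wild type, was negative for 17 genes and positive for 1. It was -5.71 ± 0.256 in log2 for mtl-1 (adjusted p = 3.92e-07), -6.98 ± 0.405 for cdr-1 (5.87e-06), -5.18 ± 0.461 for mtl-2 (0.00388) and -2.37 ± 0.318 for cdf-2 (0.0134). For ttm-1 it was -0.93 ± 0.23, which did not pass (adjusted p = 0.662). Of 66 P450 genes 4 had a negative difference, in both counts: cyp-13A4 (-5.36 ± 0.555), cyp-13A7 (-5.26 ± 0.62), cyp-14A4 (-4.26 ± 0.491) and cyp-33C7 (-2.04 ± 0.334). The same held for ugt-1 (-2.01 ± 0.285) and ugt-62 (-1.27 ± 0.187) of 62 UDP-glycosyltransferase genes, and for bcmo-2 (-2.54 ± 0.258), T16G1.6 (-2.62 ± 0.369), cpr-1 (-1.81 ± 0.265) and irg-4 (-1.52 ± 0.226). The 1 gene with a positive difference was cth-1 (1.70 ± 0.249, adjusted p = 0.0203): it fell with cadmium in the wild type and was at 0.64 in the mutant. For hrg-7 (-1.31 ± 0.214) the change was in the mutant, -1.11 against 0.20 in the wild type. For gst-38 the difference was -1.64 and did not pass (adjusted p = 0.406). Over all genes of this contrast an unadjusted p below 0.05 was seen at 513, fewer than the 791 expected by chance.

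By the definition set beforehand, 16 genes had a hizr-1-dependent response: 15 rose in the wild type with a negative interaction, and cth-1 fell with a positive one. These were 19 and 45 without wild-type replicate 1 lacking cadmium, and 34 and 51 with no filter on low counts. In 20 simulations without dependence the medians were 0 and 0, and the largest counts 1 and 2. The 1 gene that fell, cth-1, is thus within the simulated range. Genes varied independently in these simulations, so culture differences that move many genes together were not part of them. Metal-response genes as a list had 4 of 6 members with a negative interaction, or 5 adjusted over the list alone, and passed camera with an estimated correlation (adjusted p = 0.00515). Camera's preset test placed 18 lists apart. The P450 list (median -0.435) had adjusted p = 3.41e-23, and adjusted p = 0.0949 with an estimated correlation. The sperm list (median 1.86, 0 of 63 passed) had adjusted p = 2.71e-27, and adjusted p = 0.405 with an estimated correlation. In the heat shock list (median -0.029, mean -0.489) 0 of 13 genes passed, or 4 negative adjusted over the list alone. Its camera adjusted p was 0.000313, and 0.247 with an estimated correlation. Only bcmo-2, cdr-1, cyp-13A4 and mtl-1 passed in every alternative that tested them. The count of 18 became 4 or 5 without wild-type cadmium replicate 2 or 1, 10 or 7 without mutant cadmium replicate 1 or 2, and 71 (50 positive, 21 negative) without wild-type replicate 1 of the cultures lacking cadmium.

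**Figure D2:**
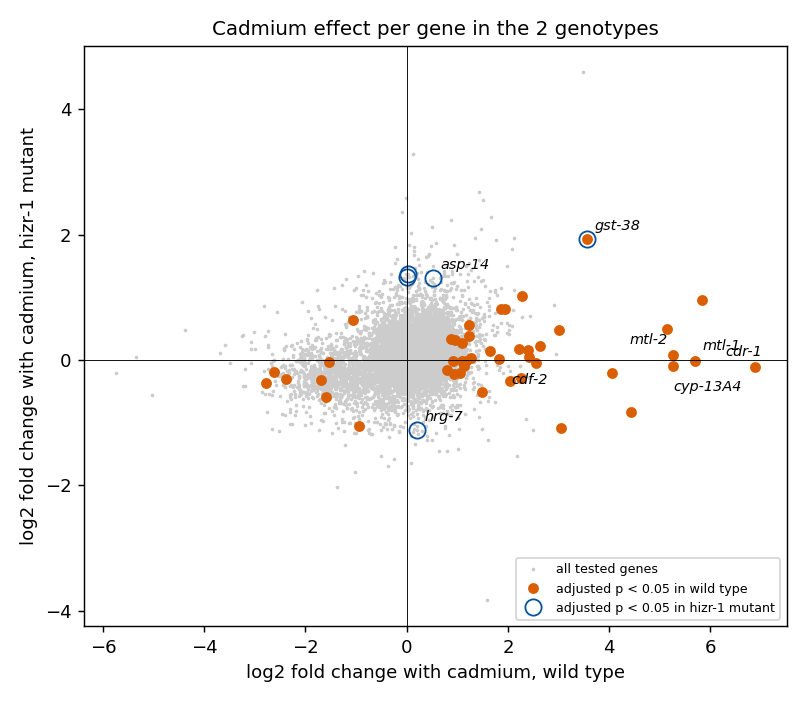
Log2 fold change with cadmium in the wild type (x axis) and in the hizr-1 mutant (y axis) for the 15818 tested genes, with genes that passed in the wild type filled and those that passed in the mutant circled. The point of cdr-1 lies at 6.87 and -0.11 and that of mtl-1 at 5.70 and -0.01, and gst-38 is the 1 gene that is both filled and circled.

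Over all 15818 genes the cadmium changes of the genotypes, which share no library, had a Pearson correlation of 0.29 and a Spearman correlation of 0.313 across genes, which are not independent replicates. The Pearson value was 0.087 and 0.103 without replicate 1 of the mutant lacking or given cadmium, 0.174 without wild-type cadmium replicate 1, and 0.03 with no filter on low counts. The 37 genes that rose in the wild type had a median log2 change of 2.05 there and 0.04 in the mutant. The 1 gene that rose in both was gst-38, against 0.00936 expected for independent lists. The lists are not fully independent, since each gene's spread came from the same fit in both contrasts.

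Without cadmium the mutant differed from the wild type at 20 genes, 14 higher and 6 lower. Higher in the mutant were the neighbouring genes pud-3, from 37.3 ± 2.3 to 246 ± 65.9 CPM (2.72 ± 0.2, adjusted p = 0.000152), and pud-4 (2.62 ± 0.302, adjusted p = 0.0147), whose bodies overlap on opposite strands. The P450 gene cyp-29A2 (3.40 ± 0.268, adjusted p = 0.000152), the ABC transporter gene pgp-8 (3.01 ± 0.289), gst-24 (2.09 ± 0.23) and the C-type lectin gene clec-52 (2.26 ± 0.283) were higher as well. Each was the 1 member of its list to pass, with 5 further lectins higher and 1 lower adjusted over the list alone. Lower in the mutant were argk-1, an arginine kinase gene (-3.08 ± 0.323, adjusted p = 0.00209), the nearby cth-1 (-1.70 ± 0.179, adjusted p = 0.00209), C35E7.5 (-1.302 ± 0.15) and mtl-2 (-2.45 ± 0.321, adjusted p = 0.0348). The genes cth-1 and argk-1 lie at V 16100655 to 16102744 and V 16103894 to 16106140.

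Basal mtl-2 was thus 10.9 ± 3.82 CPM in the wild type and 1.93 ± 0.642 CPM in the mutant, whereas mtl-1 (-0.45 ± 0.182, adjusted p = 0.385), cdr-1 (0.96 ± 0.311, 0.267), cdf-2 (0.08 ± 0.231, 0.959) and ttm-1 (0.02 ± 0.163, 0.992) did not pass. Of the 6 metal-response genes 1 was lower, or 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00139, and adjusted p = 0.727 with an estimated correlation). The sperm list lay above 0 at 62 of 63 genes with a median of 0.80 and 0 genes passed, or 3 adjusted over the list alone (camera adjusted p = 1.4e-09, and adjusted p = 0.827 with an estimated correlation). When edgeR was fitted to only the 4 libraries of this contrast 0 genes passed, with an unadjusted p below 0.05 at 1458, whereas over all 8 libraries DESeq2 called 97 and limma-voom 19. The count was 9 to 12 without any one of the libraries of the other groups or of the mutant without cadmium, except that it was 449 without wild-type replicate 2 lacking cadmium and 23 without replicate 1, and library size scaling alone gave 30 higher and 6 lower.

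With cadmium the mutant lay far below the wild type at the metallothionein genes and cdr-1, and less far at cdf-2 and ttm-1. The log2 differences were -7.63 ± 0.347 for mtl-2 (adjusted p = 2.14e-05), -6.16 ± 0.193 for mtl-1 (5.23e-09), -6.02 ± 0.279 for cdr-1 (4.16e-07), -2.29 ± 0.222 for cdf-2 (0.000272) and -0.91 ± 0.163 for ttm-1 (0.00908). All 6 metal-response genes were lower, hizr-1 included, and the list passed camera with an estimated correlation (adjusted p = 0.00394). Also lower were T08G5.1 (-5.45 ± 0.443), ilys-2 (-5.68 ± 0.593, with 5 and 0 counts in the mutant), cyp-13A4 (-4.52 ± 0.338), cyp-14A4 (-4.50 ± 0.317) and cyp-13A7 (-4.22 ± 0.391). Of 66 P450 genes 6 were lower and 1, cyp-29A2 (2.56 ± 0.255), was higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.73e-09, and adjusted p = 0.314 with an estimated correlation). Lower members of other lists were ugt-62 (-1.44 ± 0.134), ugt-1 (-1.24 ± 0.2), gst-33 (-2.25 ± 0.364), gst-38 (-1.01 ± 0.245), pgp-1 (-0.94 ± 0.175), hrg-7 (-1.11 ± 0.153), irg-4 (-0.90 ± 0.159), clec-71 (-2.404 ± 0.35), cpr-1 (-1.13 ± 0.188) and cpr-5 (-0.74 ± 0.141), whereas ugt-16, which cadmium had raised, did not pass (-0.42 ± 0.2, adjusted p = 0.488). In total 68 genes were lower.

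A larger set of 606 genes was higher in the mutant, 12 of them on the list of sperm genes. The largest changes by the rule were cyc-2.2, a cytochrome c gene (3.59 ± 0.584), ant-1.4, an adenine nucleotide translocase gene (3.32 ± 0.39), H05L14.1 (3.22 ± 0.411), F58E6.5 (3.15 ± 0.534), F47D12.7 (3.12 ± 0.46) and sss-2 (2.92 ± 0.484). The annotated body of cyc-2.2 overlaps cubn-1 on the other strand. Of 63 sperm genes 12 were higher and 0 lower, or 61 and 0 adjusted over the list alone, among them spe-4 (2.11 ± 0.271) and spe-15 (0.99 ± 0.179, overlapping gst-25 on the other strand). The median of the list was 2.66 (camera adjusted p = 1.53e-45, and adjusted p = 0.326 with an estimated correlation). The lectin genes clec-73 (2.77 ± 0.388) and clec-151 (2.32 ± 0.33) were among 6 C-type lectins that were higher of 121, and his-70 (3.25 ± 0.695) and cbs-2 (2.63 ± 0.599) were the histone and sulfide list members that were higher. Of the 606 genes 5 lay on the X chromosome, 0.825% against 14.3% of all tested genes.

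**Figure D3:**
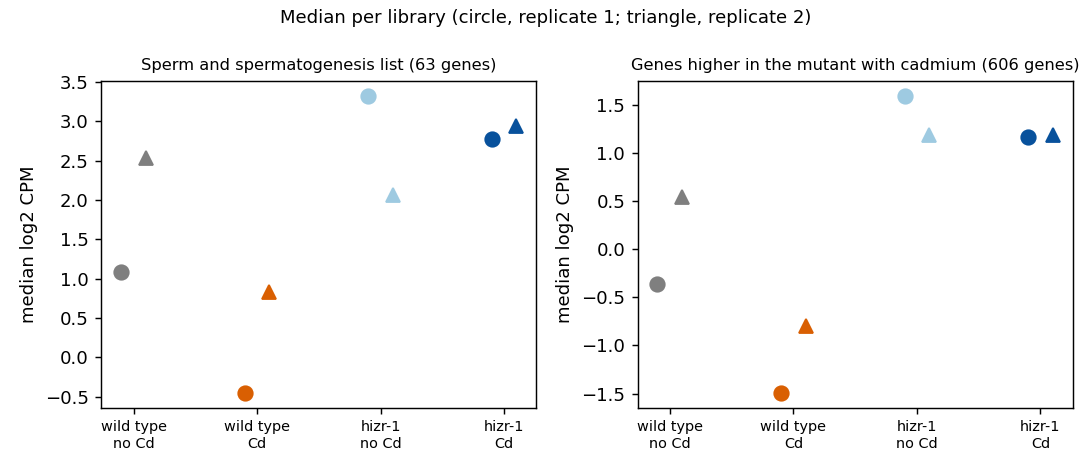
Median log2 CPM per library of the 63 sperm genes (left) and of the 606 genes higher in the mutant with cadmium (right), by group, with replicate 1 as a circle and replicate 2 as a triangle. The sperm medians run from -0.452 to 2.53 in the wild-type libraries and from 2.06 to 3.32 in the mutant libraries.

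Other lists moved with these genes in camera's preset test. Moulting markers had a median of -0.49 (3 of 20 above 0, adjusted p = 0.000208, and adjusted p = 0.728 with an estimated correlation) and neuron markers of -0.30 (2 of 23 above 0, 0.00374, and adjusted p = 0.869 with an estimated correlation). Ribosomal proteins had a median of 0.38 (75 of 76 above 0, 0.00107, and adjusted p = 0.869 with an estimated correlation), and 0 genes of these 3 lists passed. With the sperm covariate each of these 3 lists was placed on the other side of other genes. The sperm list median was 2.77 and 2.94 in the mutant with cadmium, 3.32 and 2.06 in the mutant without, and lower in both wild-type cadmium libraries (-0.452 and 0.835). In the wild type without cadmium, whose libraries this contrast does not compare, 552 of the 606 genes were lower in replicate 1 than in replicate 2, with a median difference of -0.814. The first principal component held 54.9% of the variance, with scores of 74.37 and 36.77 for the wild-type cadmium libraries, 27.41 and -13.96 for the wild type without cadmium, and -25.26 to -43.65 for the mutant. In all 674 genes passed. A fit without 1 library leaves 1 in its group, so the median log2 difference of the 606 genes is given here, 2.52 with all libraries. It was 2.07 and 3.05 without wild-type cadmium replicate 1 and 2, and 2.54 and 2.52 without mutant cadmium replicate 1 and 2. Without either wild-type library lacking cadmium it was 2.52. With the sperm list median as a covariate, a fit chosen after seeing the data, the count was 17 (3 higher, 14 lower). The median log2 difference of the 606 genes was then 1.24 in place of 2.52, with a median SE of 0.677 in place of 0.494. The list medians do not overlap between the 2 groups compared, and 12 of the 606 genes are on the list. The covariate thus takes up part of the genotype difference itself, and the lower values do not show its cause.

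Between the genotype contrasts with and without cadmium, which share no library, the Pearson correlation across genes was 0.639 and the Spearman correlation 0.383. The Pearson value fell to 0.319 and 0.383 without replicate 1 of the wild type or the mutant lacking cadmium, and to 0.144 with no filter on low counts. Higher in both were 13 genes, among them pud-3, pud-4, cyp-29A2, pgp-8, gst-24 and clec-52, against 0.536 expected for independent lists. Lower in both were 4 genes, mtl-2, C35E7.5, asp-17 and lips-6, against 0.0258 expected, the last 2 named after their values were seen. Both contrasts took each gene's spread from the same fit, so the lists are not fully independent. The 13 and 4 together became 4 without wild-type cadmium replicate 1, 7 to 10 without any one of the other cadmium or mutant libraries, and 387 without wild-type replicate 2 lacking cadmium.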

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

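The explanations below were written down after the calls and the principal components had been seen and before their own tests were run, while the tests chosen after the result was seen were thinning, the sperm covariate and the fold without a library. For 18 genes the test of the difference between the genotypes' cadmium responses passed, which is why they are given here. The differences (mutant minus wild type, log2) were -5.708 for mtl-1, -6.976 for cdr-1, -2.538 for bcmo-2, -5.357 for cyp-13A4, -4.26 for cyp-14A4, -5.175 for mtl-2, -5.261 for cyp-13A7, -2.367 for cdf-2 and -2.615 for T16G1.6. They were -2.005 for ugt-1, -1.808 for cpr-1, 1.695 for cth-1, -1.268 for ugt-62, -4.134 for bcmo-1, -1.517 for irg-4, -2.382 for thn-2, -1.309 for hrg-7 and -2.041 for cyp-33C7.

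The 606 genes higher in the mutant with cadmium were weighed first. Fewer animals making sperm in the wild-type cadmium cultures stays open: between 2 cultures of a group the sperm list median differed by 0.544 of the genotype difference in the wild type without cadmium, which this contrast does not compare, and by 0.483 and 0.0623 in the wild type and the mutant with cadmium, against the 0.5 set beforehand for any group. For a single library the test does not decide. Without wild-type cadmium replicate 1 the count of higher genes fell under the limit set beforehand, the main count divided by 2. The fold, looked at after that result, mostly stayed, but the 606 genes had been picked in a fit with that library. With 1 wild-type cadmium library left, their median log2 difference went from 2.52 (median SE 0.494) to 2.07 (0.571). Without wild-type cadmium replicate 2, which also left 1 library, that median was 3.05 (median SE 0.608). The difference was thus larger with replicate 1 as the library left than with replicate 2. Unequal depth does not account for the 606 genes, as 496 were higher after thinning, 466 of them among the 606. The tests do not separate an effect of hizr-1 on the germ line from cultures that differed in stage or sperm content.

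The 17 genes that differed between the genotypes both with and without cadmium were weighed next. Variants on chromosome X carried along with the allele do not account for the whole set by changing genes on that chromosome. Of the 17 genes 1 lies there, 5.88% against 14.3% of tested genes (one-sided Fisher p = 0.928). It is pgp-8 at 10859351 to 10864422, and hizr-1 lies at 11318278 to 11321076. Effects of such variants on genes of other chromosomes, and variants on other chromosomes, remain possible and were not tested. Unequal depth does not account for the 17 genes, as 12 of the same 17 passed after thinning and 0 others did.

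The cadmium response left in the mutant was weighed last. Of the 50 genes with the smallest p in the mutant, 41 changed in the same direction in the wild type (82%, 95% interval 68.6 to 91.4, binomial p = 2.81e-06, with genes that are not independent). The share met the prediction of a cadmium response that does not need hizr-1, but it was set against equal odds of either direction. Over all 15818 genes the cadmium changes of the genotypes already had a Spearman correlation of 0.313. The same-direction share over all genes was not computed, so the test does not decide. The gene gst-38 passed in both genotypes. Its log2 change in the mutant was 1.526 to 2.237 over 21 alternatives, and in 12 of them it no longer passed. For cultures that differed by chance the test cannot tell: the 5 genes that passed had a median change of 0.0205 in the wild type, counted in the direction of the mutant, and 0 of them were on the lists of cell types and stages.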

How the results depend on the processing

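Groups of 2 limit every test here, and a library left alone in its group was assumed to vary like the other groups. No gene that passed passed in the opposite direction under an alternative, but of 64 list results 12 did: 10 with the sperm covariate (ribosomal, histone, moulting and neuron lists), 1 without wild-type replicate 2 lacking cadmium and 2 without mutant replicate 2 lacking cadmium (ribosomal list, once on a result already counted). Of the counts and correlations 200 stayed the same and 134 moved, and of the single-gene results 2360 stayed on their side of the threshold, 572 no longer passed and 6 newly passed. Except where fewer genes, samples or a stricter threshold were used by construction, the cause was not tested. In the order cadmium in the wild type, cadmium in the mutant, genotype without cadmium, genotype with cadmium and interaction, the counts were 45, 5, 20, 674 and 18. There were 16 genes with a hizr-1-dependent response, 1 and 17 genes passed in both cadmium and in both genotype contrasts, and 17, 8, 8, 13 and 18 lists passed.

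RLE size factors gave 3 genes for cadmium in the mutant. Library size only gave 36 genes, 28 shared and 13 lists for genotype without cadmium. With no filter on low counts the 5 counts were 576, 21, 630, 1188 and 90 (interaction 55 positive, 35 negative), with 85 dependent, 9 and 448 shared, 15 lists for genotype without cadmium, and correlations of 0.03 and 0.144. The stricter filter gave 15 and 1 for cadmium, 9 dependent, 0 shared and 17 lists. DESeq2 gave 215, 11, 97 and, for the interaction, 28, with 25 dependent and 4 and 75 shared. By limma-voom cadmium in the mutant had 1 gene and 0 were shared, and so it was for protein-coding genes only (13 lists for genotype without cadmium) and after thinning. With 1 surrogate variable the counts were 23, 0, 10, 403 and 10, with 10 dependent, 0 and 8 shared, 15 lists and a correlation of 0.179. The sperm covariate gave 23, 10, 37 and 17, with 2 and 6 shared and 15 lists. The contrast's own samples gave 399, 0, 0 and 1288, and 13 lists for genotype without cadmium. At adjusted p under 0.01 the counts were 20, 0, 8, 205 and 7, with 7 dependent and 0 and 5 shared. An estimated correlation left 1, 0, 0, 1 and 1 lists, and fry 3, 0, 1, 2 and 1.

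With single libraries left out the 5 counts ranged from 17 to 423, 0 to 14, 9 to 449, 24 to 1059 and 4 to 71. Dependent genes ranged from 4 to 64, shared genes from 0 to 3 and 4 to 387, and lists from 13 to 19, 8 to 11, 8 to 15, 12 to 15 and 13 to 22. The correlations ranged from 0.087 to 0.31 and 0.319 to 0.689.

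What same-numbered replicates of the groups share beyond the number is not known. Their deviations correlated at 0.42, -0.431, -0.006, -0.102, 0.122 and 0.043, and replicate 1 had the larger total count in every group. With 2 libraries per group these correlations cannot exclude pairing. A replicate block gave 0 genes for cadmium in the mutant, 12 for genotype without cadmium, and 0 and 10 shared, and kept the other counts within 1.5 times.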

Other observations

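The cysteine enzyme gene cth-1 had 57.7 ± 10 CPM in the wild type without cadmium, 27.8 ± 1.34 with cadmium, and 17.8 ± 1.65 and 27.8 ± 1.89 CPM in the mutant without and with cadmium (SD, n = 2). The nearby argk-1 had 17.5 ± 4.35, 7.22 ± 1.72, 2.1 ± 0.815 and 4.74 ± 0.802 CPM in the same order. The interaction of argk-1 was 2.46 ± 0.434 and did not pass (adjusted p = 0.0898). The metal-response gene numr-1 had 0 counts in all 8 libraries. How reads that match both it and its near-identical copy numr-2 were counted is not known, so numr-1 could not be evaluated.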
